A study of Homo sapiens with 4 samples.

How the data were processed

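MDA-MB-231 is an established human breast cancer cell line and MDA-LM2 is its highly lung-metastatic derivative. Per the labels' protocols, total RNA was extracted with a column kit that included DNase treatment on the column, and libraries were made with ScriptSeq v2. The labels give 4 samples in 2 groups, with replicates 1 and 2 in each, and do not say whether the replicates came from separate cultures. Alignment with STAR 2.7 to hg38 is per the submitters' processing notes. Skipped-exon events were quantified with MISO, per the file headers. The MISO version, its settings, the event annotation, and whether and how the replicates were combined are not given in the sources used here.

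The 3 deposited files hold 1 table per cell line and 1 table that compares them. Each cell line's table names no replicate and is taken here, and called, pooled over the line's samples, which the sources used here do not state. Per the file headers, each cell line's table gives the inclusion level of an exon as a fraction from 0 to 1, the posterior mean of MISO, with the bounds of an interval whose level is not given in the sources used here. The same deposited tables give raw read counts per event in 4 classes, the reads that fit the inclusion isoform, the exclusion isoform, both or neither. Each listed event had at least 20 reads in all classes together, and 74.7% of listed reads in LM2 and 75.7% in parental cells fit neither isoform. In the authors' deposited table of the comparison, the difference is a score that equals the LM2 level minus the parental level in each event. The Bayes factor in the authors' deposited table is a ratio, the odds of a difference over no difference, and is capped in the file. A pooled value per line carries no replicate error, so no p-value for a difference between the lines is given, and the tests of reads described below compare the pooled libraries only.

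The choices in this paragraph were made before the data were examined, except where said otherwise. An exon was called higher or lower in LM2 with a Bayes factor of at least 10 and a difference in inclusion level of at least 0.2. Events entered with at least 10 inclusion plus exclusion reads in each library and at least 1 of each kind over both, and each skipped exon was represented by its event with most such reads. This left 15296 of 39160 compared events and 14109 of 33165 exons. The median width of the deposited interval was 0.11 in LM2 and 0.10 in parental cells for the exons tested. Exon coordinates are those of the files, in hg38, and 31676 exons matched an exon of GENCODE release 29 exactly. Genes were assigned where the exon lay inside a gene on the same strand, and 12960 tested exons lay in 1 gene. The named exons were the 12 largest increases and the 12 largest decreases with at least 20 informative reads in each library and 1 exon per gene, up to 4 changed exons per gene list, and the best covered exon of PLEC, SNRPA1 and CD44. Exons in overlapping genes were not named among the largest changes, and 1 exon that the rule selects is not reported here.

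A read-based inclusion level was computed as inclusion reads divided by 2, over that value plus exclusion reads. It uses no reads that fit both isoforms and takes no account of exon length. A read-based difference of at least 0.1 in the same direction was added as a check after the data were seen, and a rise of that size is not possible where the parental level is above 0.9. The ratio between libraries of the odds of inclusion over exclusion reads, with its exact conditional 95% interval, was therefore also set against the odds ratio of the deposited levels, which were bounded at 0.005 and 0.995. For the value of the read ratio 0.5 was added to each count, and the interval used the counts as they were. Two-sided Fisher's exact tests on inclusion and exclusion reads, with Benjamini-Hochberg adjustment at 0.05 and a read-based difference of at least 0.2, compare the pooled libraries and not the lines. The test was checked on simulated reads at the depth of the 14109 exons with a threshold of 0.1. It called 18 of 100 exons changed by 0.2, 38 of 100 changed by 0.4 and 0 of 13909 unchanged exons. Among simulated exons with at least 50 reads in each library it called 45.9% of those changed by 0.2 and 91.7% of those changed by 0.4. The simulated reads varied by counting error only, so the lack of calls in unchanged exons says nothing of other variation. Changes were planted in exons of intermediate level, and the threshold of 0.1 is looser than the 0.2 used on the real reads. The shares called are therefore not those of the real test.

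The 10 gene lists were U2 snRNP and core spliceosome, SR proteins and SR kinases, hnRNPs and splicing regulators, epithelial-mesenchymal splicing targets, cytoskeleton and adhesion, lung metastasis signature, apoptosis and cancer-linked isoforms, membrane traffic, chromatin and transcription, and markers of other cell types. A list's median difference and its share of changed exons were given as percentiles among 10000 random sets matched on deciles of reads. Some members of the lung metastasis signature were first described in these cell lines, so that list is not independent of them. A list of interferon-stimulated genes was chosen after the data were seen, and was used with and without the lower genes that prompted it (BST2, HLA-B, TNFSF10, CD74 and CD40).

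Transcript level was described from the inclusion, exclusion and shared reads of a gene's best covered event, scaled to the total of such reads over all compared events (17360655 in LM2 and 21693677 in parental cells), for genes with at least 20 reads over both libraries. Ratios have exact conditional 95% intervals for 2 Poisson counts. Named genes were up to 4 per list with a ratio of at least 2 or at most 0.5 and an interval that excluded 1. Reads are not independent molecules, so intervals cover counting error only. Exon length, GC content and lengths of flanking introns were compared with matched sets of tested exons. GC content came from the sequences of annotated transcripts and was known for 95.2% of tested exons. Sequence features of the flanking introns were not analysed here.

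Alternatives were other thresholds of difference and Bayes factor, other read minimums, the read filter of MISO, every event or 1 exon per gene, intervals that do not overlap, Fisher's exact test with and without thinning of the deeper library, read-based levels, scaling by the median gene, and unmatched background sets. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.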

Results

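The series compared MDA-MB-231, a human triple-negative breast cancer cell line, with MDA-LM2, a derivative of that line that colonises the lung at high rates. Total RNA from 2 samples of each line was sequenced. The deposited files give 1 set of skipped-exon quantities per line, taken here as a pooled library. No replicate check was therefore possible, and no p-value across genes or exons is given. The question was how exon use differed between the poorly and the highly metastatic population. The LM2 file listed 39981 skipped-exon events, with 4701744 reads that fit the isoform including the exon and 955034 that fit the isoform lacking it. The parental file listed 43626 events, with 5529885 inclusion reads and 1101330 exclusion reads. A further 11709827 reads in LM2 and 15085722 in parental cells fit both isoforms. After the read minimum, 14109 skipped exons in 6546 genes could be compared, with a median of 74 informative reads per exon in LM2 and 92 in parental cells.

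Exon inclusion differed between the lines at a small set of exons. With at least 20 informative reads in each library and outside overlapping genes, the largest increases in LM2 were in NIN, which encodes the centrosomal protein ninein, and in ATG13, a component of the complex that starts autophagy. The NIN exon had an inclusion level of 0.83 (interval 0.79 to 0.88) in LM2 against 0.30 (0.29 to 0.32) in parental cells, and the ATG13 exon 0.75 (0.51 to 0.95) against 0.23 (0.11 to 0.39). Under the same rule the largest decreases were in RIPOR1, at 0.28 (0.15 to 0.45) against 0.85 (0.64 to 0.99), and in MFSD8, a lysosomal membrane protein, at 0.27 (0.18 to 0.37) against 0.73 (0.58 to 0.91). By the authors' deposited table, 130 exons were higher and 46 lower in LM2 with a Bayes factor of at least 10 and a difference of at least 0.2, which is 1.25% of the exons compared. Of these 176 exons, 73.9% were higher in LM2 (exact Clopper-Pearson 95% interval 66.7 to 80.2, counting error only). The median difference over all compared exons was 0, with quartiles of -0.02 and 0.03. Among the higher exons 96 were coding and 16 lay in 5′ untranslated regions, and among the lower exons 36 were coding and 4 lay in 5′ untranslated regions.

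Among the exons higher in LM2, the NIN exon is a coding exon of 2139 nt on chromosome 14, positions 50756492 to 50758630 of hg38. The ATG13 exon of 194 nt (chromosome 11, 46629907 to 46630100) matched no annotated exon exactly. A 79-nt coding exon of PRKRIP1 (chromosome 7, 102397620 to 102397698) had an inclusion level of 0.86 in LM2 against 0.35, with 0 exclusion reads in LM2 and 5 in parental cells. The coding exon of NFIC, a nuclear factor I transcription factor, was at 0.84 against 0.36, that of TRAPPC1, a vesicle tethering subunit, at 0.84 against 0.37, and that of SLC8B1, the mitochondrial sodium-calcium exchanger, at 0.93 against 0.48. JMJD1C was at 0.90 against 0.50, and CHFR, a mitotic checkpoint ubiquitin ligase, at 0.60 against 0.21. HDAC1, a histone deacetylase, was at 0.97 against 0.59, and NAA40, an N-terminal acetyltransferase, at 0.71 against 0.33. Exclusion reads were 4 in LM2 against 1 in parental cells for TRAPPC1, 2 against 0 for CHFR and 0 against 1 for JMJD1C. They were 0 against 2 for NFIC, SLC8B1 and HDAC1, and 2 against 10 for NAA40. Of the 12 largest increases 9 had under 10 exclusion reads over both libraries, as had 6 of the 12 largest decreases. A 5′ untranslated exon of 153 nt in TEAD1, a transcription factor of the Hippo pathway (chromosome 11, 12675409 to 12675561), was at 0.85 (0.80 to 0.89) against 0.47 (0.41 to 0.54). Its reads were 459 inclusion and 29 exclusion in LM2, against 216 and 30 in parental cells.

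Among the exons lower in LM2, the RIPOR1 exon is a 223-nt coding exon (chromosome 16, 67529637 to 67529859) with 13 inclusion and 9 exclusion reads in LM2 against 22 and 0 in parental cells. A 45-nt coding exon of EXOC1, a subunit of the exocyst (chromosome 4, 55888888 to 55888932), fell to 0.14 (0.07 to 0.22) from 0.47 (0.37 to 0.58), and its inclusion reads were 7 against 48 while exclusion reads were 34 in each library. An 84-nt coding exon of ADGRG6, an adhesion G protein-coupled receptor (chromosome 6, 142383760 to 142383843), was at 0.65 against 0.94 with 21 against 3 exclusion reads. SSBP4 was at 0.20 against 0.56 with 26 against 14 exclusion reads. The 5′ untranslated exon of INTS12, an Integrator subunit, was at 0.20 against 0.60, and that of ACSL4, a long-chain acyl-CoA synthetase, at 0.49 against 0.85. SKA3, a kinetochore protein, was at 0.45 against 0.84, TBL1X, a corepressor subunit, at 0.22 against 0.59, and ARHGAP17, a GTPase-activating protein, at 0.37 against 0.67. GOLT1B was at 0.61 against 0.95 and SETMAR at 0.62 against 0.95, each with 1 exclusion read in LM2 and 0 in parental cells.

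**Figure D1:**
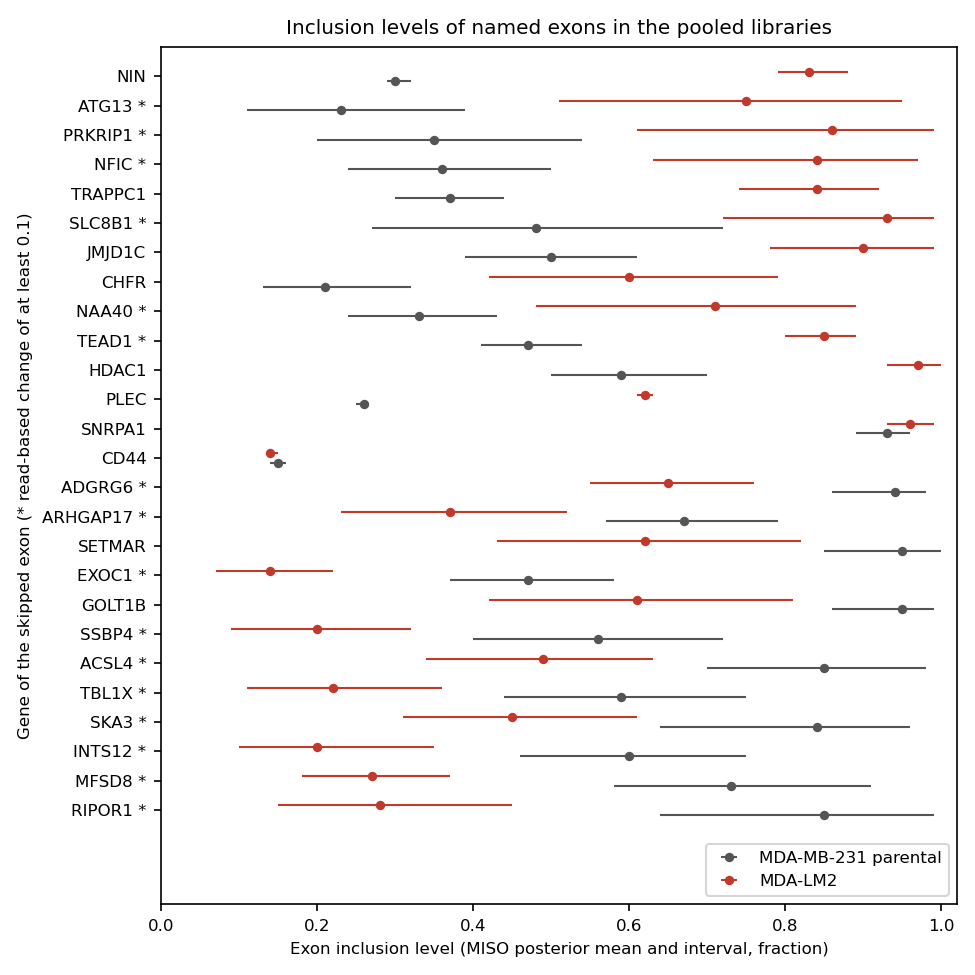
Inclusion level (fraction, x axis) of the skipped exon in each named gene (y axis) in the pooled MDA-LM2 library (red) and the pooled parental library (grey), as points for the MISO posterior mean with the deposited interval as bars. NIN lies at 0.83 against 0.30 and RIPOR1 at 0.28 against 0.85, while SNRPA1 lies at 0.96 against 0.93; an asterisk marks a change of at least 0.1 in the same direction from inclusion and exclusion reads alone.

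PLEC, which encodes the cytoskeletal linker plectin, had the most reads among the named exons. This coding exon of 3381 nt on chromosome 8 (143922504 to 143925884) had an inclusion level of 0.62 (0.61 to 0.63) in LM2 and 0.26 (0.25 to 0.26) in parental cells. It carried 17717 inclusion and 102 exclusion reads in LM2, against 6592 and 18 in parental cells, so that the level computed from those reads alone was 0.989 against 0.995. CD44, a receptor for hyaluronan, had a 63-nt coding exon (chromosome 11, 35214852 to 35214914) at 0.99 (0.98 to 1.0) against 0.64 (0.61 to 0.68), where reads alone gave 0.997 in each library, from 4 exclusion reads in LM2 and 3 in parental cells. The best covered CD44 exon, of 204 nt (35211246 to 35211449), stood at 0.14 against 0.15, where reads alone gave 0.368 against 0.502. SNRPA1, a U2 snRNP protein, had an 80-nt coding exon at 0.96 (0.93 to 0.99) against 0.93 (0.89 to 0.96), with a Bayes factor of 0.18 in the authors' deposited table.

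A level computed from inclusion and exclusion reads alone gave a partial check of these calls. Of the 46 lower exons, 38 had a read-based difference of at least 0.1 in the same direction, among them RIPOR1, EXOC1, INTS12 and TBL1X, and of the 130 higher exons 52 did, among them ATG13, PRKRIP1 and TEAD1. For TEAD1 the read-based difference was 0.105, just past the limit and well short of the deposited 0.38. The counts of 38 and 52 cannot be compared with each other, because 66 of the higher exons had a read-based level above 0.9 in parental cells. A rise of 0.1 is not possible there, and no lower exon had the matching limit. NIN, TRAPPC1, JMJD1C, CHFR, HDAC1, PLEC and the 63-nt exon of CD44 are among the 66, as is every higher exon named below as lacking such a difference. Where the mean read-based level of the 2 libraries was 0.1 to 0.9, 46 of 53 higher and 36 of 36 lower exons had the difference. That range is partly set by the change itself. Lower exons near full inclusion whose reads hardly fell, such as GOLT1B and SETMAR, lie outside it, so 36 of 36 is not a separate check. EXOC7, with no room for a rise of 0.1, lies inside it. The odds of inclusion over exclusion reads are not bound by the limit at 0.9. With 0.5 added to each count, their ratio between libraries moved in the direction of the call for 101 of the 130 higher and 45 of the 46 lower exons. Where exclusion reads are few, the added 0.5 or the inclusion reads can set that direction. The 63-nt exon of CD44, with 4 exclusion reads in LM2 against 3, counted as moved with the call (log2 ratio 0.22). The direction is therefore not an independent check of skipping. The median log2 odds ratio of the higher exons was 1.41 from reads and 2.11 from the deposited levels, and that of the lower exons -2.30 and -2.35. For NIN, with 10 exclusion reads in LM2 against 62, the 2 values were 3.55 and 3.51. Fisher's exact test of inclusion against exclusion reads, which compares the 2 pooled libraries and not the lines, also called 14 of the higher and 7 of the lower exons. SSBP4, EXOC1 and ADGRG6 were among the latter, and none of the 12 largest increases was called. The test also needed a read-based difference of 0.2, which is out of reach where the parental read-based level is above 0.9.

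**Figure D2:**
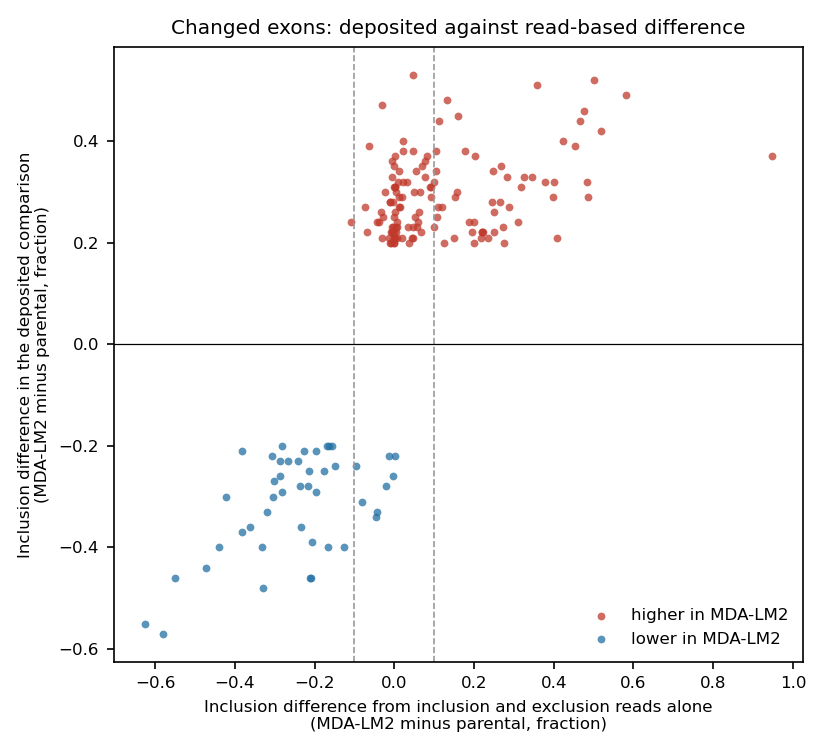
Inclusion difference in the deposited comparison (y axis, MDA-LM2 minus parental, fraction) against the difference computed from inclusion and exclusion reads alone (x axis, same unit) for the 130 exons higher (red) and 46 exons lower (blue) in MDA-LM2; dashed lines mark differences of -0.1 and 0.1. Of the red points 52 lie at or beyond the line at 0.1, and of the blue points 38 lie at or beyond the line at -0.1; 66 red points could not reach it, since their parental read-based level was above 0.9.

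Genes known for splicing differences between epithelial and mesenchymal cells held a larger share of changed exons than most matched sets. The sets were matched on reads alone and not on inclusion level, so exons of these genes may have had more room to change. Of all 142 exons tested in 48 of these genes, not limited to exons known to differ, 3 were higher, 3 were lower and 136 were not changed, and the changed share lay at the 99.2 percentile of 10000 random sets of exons matched on reads. A 63-nt coding exon of MPRIP, a myosin phosphatase partner, was at 0.73 in LM2 against 0.52, and an exon of EXOC7 at 0.42 against 0.18 beside the 63-nt exon of CD44. EXOC1 was lower, as were SYTL2, a RAB27 effector (0.29 against 0.75), and KIF13A, a kinesin (0.16 against 0.43). All 3 lower exons and the MPRIP exon had a read-based difference of at least 0.1, and the EXOC7 and CD44 exons did not. The share from these 4 exons alone lay at the 99.6 percentile of matched sets, a test added after the data were seen. That test reuses exons already counted above and is not separate support. The list's median difference was 0.01, at the 99.1 percentile.

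Of 228 exons tested in cytoskeleton and adhesion genes, 5 were higher and 1 was lower in LM2, a share at the 94.8 percentile of matched sets. A 130-nt coding exon of ITGA6, the laminin receptor subunit integrin alpha 6 (chromosome 2, 172501772 to 172501901), was at 0.85 against 0.63, with 4787 inclusion and 649 exclusion reads in LM2 against 1787 and 774 in parental cells. A 102-nt coding exon of PXN, which encodes paxillin, was at 0.39 against 0.19. PTK2, which encodes focal adhesion kinase, had a 5′ untranslated exon at 0.61 against 0.33 and a coding exon at 0.94 against 0.67, neither with a read-based difference of 0.1. ITGA6 and PXN are named after their values were seen, as are MPRIP and EXOC7. In membrane traffic genes, 2 of 146 exons were higher and 2 lower (92.9 percentile). They were in ASAP2 (0.72 against 0.42) and ASAP1 (0.64 against 0.40), which regulate ARF GTPases, and in the golgin GOLGA4 (0.18 against 0.39) and the syntaxin STX2 (0.28 against 0.48), and all but the ASAP1 exon had a read-based difference of 0.1.

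Changed exons of splicing factor genes were within the range of matched sets. None of 82 exons of U2 snRNP and core spliceosome genes passed, nor any of 143 exons of hnRNPs and other splicing regulators, and these shares of 0 lay at the 17.3 and 7.31 percentiles. Of 71 exons of SR protein and SR kinase genes, 1 passed, in RSRC1 (0.82 against 0.51), with 1 exclusion read in each library (55.8 percentile). At a difference of 0.1, 1 U2 and core spliceosome exon, 5 hnRNP and regulator exons of 143 and 3 SR exons of 71 passed, against 2.07% of all tested exons (24.3, 65.9 and 77.2 percentiles). None of 26 exons of lung metastasis signature genes passed (36.2 percentile). In apoptosis and cancer-linked genes 2 of 131 exons were higher (64.7 percentile), in RPS6KB1 (0.91 against 0.61), the ribosomal S6 kinase, and in ATM (0.95 against 0.72), the DNA damage kinase, neither with a read-based difference of 0.1. In chromatin and transcription genes 2 of 216 were higher, TEAD1 and the histone methyltransferase NSD2 (0.71 against 0.43), and 1 was lower, in the macroH2A gene H2AFY (0.70 against 0.96), at the 58.6 percentile; of these the TEAD1 exon had a read-based difference of 0.1. Apart from the list of epithelial-mesenchymal targets, each list with tested exons had a median difference of 0. No exon of the genes chosen as markers of other cell types could be tested.

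Exons higher in LM2 were followed by long introns, with a median of 3674 nt against 2221 nt over all tested exons, at the 99.96 percentile of sets matched on reads, and for the lower exons the median was 2801 nt (79.4 percentile). Upstream introns had medians of 2590.5 nt in higher and 3064.5 nt in lower exons, against 2296 nt (75.3 and 84.2 percentiles). Lengths divisible by 3 made up 50% of the higher and 54.3% of the lower exons, against 41.8% of tested exons (96.3 and 96.2 percentiles). Median GC content was 49.9% in higher exons and 46.9% in lower exons, against 48.1% over tested exons (95.9 and 23.0 percentiles). Median exon length was 125 nt in higher and 123 nt in lower exons, against 119 nt (82.6 and 75.8 percentiles).

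Reads at skipped-exon events gave a view of transcript level for 8818 genes. The cytoskeletal adaptor EPB41L3 had 1284 reads at its best covered event in LM2 against 2 in parental cells, a ratio of 802 after scaling to library totals (95% interval 222 to 6631). The guidance receptor ROBO1 had 78 against 3 (ratio 32.5, 10.7 to 161) and the transcription factor MEF2C 659 against 34 (ratio 24.2, 17.2 to 35.3). Lower in LM2 were the splicing regulator RBM47, with 3 reads against 186 (ratio 0.0202, 0.00412 to 0.0598), the invariant chain CD74, with 15 against 658 (0.0285, 0.0159 to 0.0473), and the matrix protein TNC, with 23 against 397 (0.0724, 0.0454 to 0.110). In all, 296 genes were at least 2-fold higher and 792 at least 2-fold lower with an interval that excluded 1. The median log2 ratio over genes was -0.12, and relative to that median 389 genes were higher and 648 lower, so the higher share was 37.5% in place of 27.2%. These intervals cover counting error only, and each ratio compares 1 pooled library with another.

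RBM47 aside, no gene of the splicing factor lists differed 2-fold in event reads. None of 35 measured U2 and core spliceosome genes and none of 27 SR protein genes differed 2-fold, and their median log2 ratios relative to the median gene were 0.20 and 0.15 (91.9 and 78.6 percentiles of random lists matched on reads). SNRPA1 had 434 reads in LM2 against 412, a ratio of 1.32 (1.15 to 1.51), or 0.52 on the log2 scale relative to the median gene. RBM47 was the 1 of 44 hnRNPs and splicing regulators past 2-fold (list median 0.17, 88.9 percentile). The ratio was 1.59 (1.57 to 1.60) for PLEC and 0.877 (0.865 to 0.888) for CD44.

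Cytoskeleton and adhesion genes were on the low side, with 4 of 71 higher, 8 lower and a list median of -0.13 relative to the median gene (0.20 percentile). EPB41L3 and TNS3, the focal adhesion protein tensin 3 (4.17, 3.03 to 5.85), were higher, as were ITGA6 (27325 reads against 14144, ratio 2.41) and its partner ITGB4 (2.65), named after their values were seen. ANK3, an ankyrin (0.221, 0.116 to 0.394), and ARHGEF10L (0.263, 0.0651 to 0.792) were lower. Membrane traffic genes had a median of -0.17 (0.53 percentile), with TBC1D1 (0.422, 0.344 to 0.514) and VPS13D (0.478, 0.330 to 0.682) lower; VPS13D was no longer 2-fold lower relative to the median gene, at -0.94 on the log2 scale. The epithelial-mesenchymal targets held no gene past 2-fold among 49 (median -0.02, 18.5 percentile).

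Of 21 measured lung metastasis signature genes, 3 were higher and 4 lower (median 0.16, 86.8 percentile). The tryptophan pathway enzyme KYNU (3.53, 2.79 to 4.50), ROBO1 and the receptor kinase MERTK (3.53, 3.16 to 3.94, named after its value was seen) were higher, and TNC and the decoy receptor TNFRSF11B (0.212, 0.121 to 0.352) were among the lower. In apoptosis and cancer-linked genes 2 of 48 were higher and 3 lower (median 0.11, 78.8 percentile), with the telomerase subunit TERT at 2.7 (1.53 to 4.92), the insulin receptor INSR at 0.203 (0.136 to 0.295), TP63 at 0.192 (0.0665 to 0.457) and ERBB2 at 0.375 (0.314 to 0.445). The DNA methyltransferase DNMT3B (2.16, 1.81 to 2.58) and MEF2C were the 2 chromatin and transcription genes higher among 63 (median -0.05, 9.03 percentile). Among markers of other cell types, 5 of 28 genes were measured and 3 were lower, CD74, PDGFRB (0.147, 0.0516 to 0.343) and GATA3 (0.285, 0.143 to 0.527), with a median of -1.69 (0.12 percentile).

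**Figure D3:**
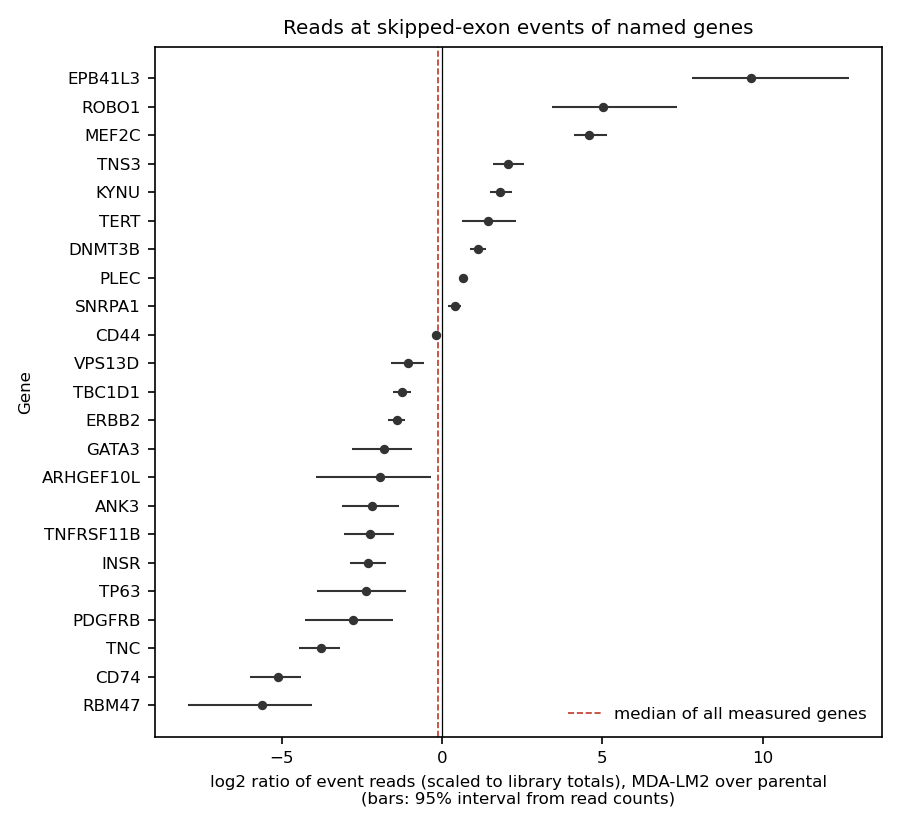
Log2 ratio of event reads scaled to library totals, MDA-LM2 over parental (x axis), for the named genes (y axis), with bars for the 95% interval from read counts and a dashed line at the median of all 8818 measured genes (-0.12). EPB41L3 had 1284 reads against 2 and RBM47 had 3 against 186, while SNRPA1 had 434 against 412 and lies above the line.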

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

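This test was chosen after the data were seen. Events listed for a single line did not enter the comparisons, and 47 events in 27 genes had at least 20 event reads in LM2 and were not listed for parental cells. They included EPB41L3 (up to 1275 reads), SLAMF7 (277), MCTP2 (76), the aldehyde dehydrogenase ALDH3A1 (71) and ROBO1 (67). Parental cells had 164 such events in 102 genes, among them the signalling regulator RGS4 (828), the protease inhibitor SERPINA1 (412), RNF180 (282), IFI27 (230), RBM47 (219) and the formyl peptide receptor FPR1 (202). Why an event is missing from a table is not given in the sources used here, and no explanation was tested.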

How the results depend on the processing

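The alternatives chosen after the data were seen are the read-based difference (lists included), the minimum of exclusion reads, the mean read-based level and the clusters of overlapping exons. More exons were higher than lower in LM2 under every alternative run, from 57.8% with the read-based difference to 83.5% with at least 50 reads, where 18 exons were lower. Counts of higher and lower exons were 205 and 87 at a difference of 0.1, 55 and 21 at 0.3, 65 and 20 at a Bayes factor of 100, 213 and 77 with no read minimum, and 55 and 19 with 1 exon per gene. They were 61 and 28 with at least 10 exclusion reads, and with the read-based difference 52 exons were higher. That alternative removes by construction 66 higher exons whose parental read-based level was above 0.9, so its share is not a fair measure of direction. Among exons with a mean read-based level of 0.1 to 0.9, a range partly set by the change itself, 53 were higher and 36 lower (59.6% higher). Fisher's exact test called 23 and 12 (65.7% higher), of which 21 were shared with the Bayes factor, and 22 and 9 with the parental library thinned. A looser threshold admits more exons and a stricter one fewer by construction; for the share that moved with the mean read-based level, with Fisher's exact test and with at least 50 reads, the cause was not tested. Of 41 named exons, the read-based difference kept 15, weakened 19 and moved 1. A changed exon counted as kept at 0.2 or more in the same direction, whatever the loss in size, and as weakened below 0.2. MFSD8 (-0.46 to -0.2119) thus counted as kept and GOLGA4 (-0.21 to -0.1953) as weakened. The best covered exons of SNRPA1 and CD44, not called changed, counted as moved where the difference shifted by more than the wider deposited interval. The read-based difference changed sign for TRAPPC1 (-0.0301), CHFR (-0.0645), PLEC (-0.0060), the 5′ untranslated exon of PTK2 (-0.0116), ASAP1 (-0.0379) and NSD2 (-0.0099), and the cause was not tested. The mean over events kept 40 of the 41 by the same rule, although JMJD1C fell from 0.40 to 0.23 and ATG13 from 0.52 to 0.3967. Genes at least 2-fold higher or lower were 184 and 419 with at least 100 reads, where fewer genes enter. Median scaling left the direction of all 23 named genes as it was. Depth limits the reads that tell isoforms apart, with a median of 74 in LM2. No paired analysis was possible because the files hold 1 pooled value per line, and leaving out each replicate was not run for the same reason. Sequence features of flanking introns were not run, since no genome sequence was used here.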

Other observations

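The tests of read support, of a general rise in inclusion, of less skipping of the PLEC exon and of the interferon response were chosen after the results were seen, and so were the genes named here and the percentile of 50 above which the interferon explanation would have been excluded, first set at 25. The tests of read support and of a general rise first used the read-based difference of 0.1, with 60.0% of higher calls lacking it and 57.8% of the exons that had it being higher, and were replaced because 66 higher exons near full inclusion could not reach it. Changes in exon use that both the Bayes factor and Fisher's exact test called involved 21 exons in 20 genes. Higher in LM2 were a 30-nt coding exon of PPP3CB, a catalytic subunit of calcineurin (0.70 against 0.38), an 83-nt coding exon of LTA4H, the leukotriene A4 hydrolase (0.80 against 0.58), and a 110-nt exon of non-coding SAT1 transcripts (0.51 against 0.20); SAT1 encodes a polyamine acetyltransferase. The same held for DHX30, an RNA helicase (0.34 against 0.12), DBF4B, a replication kinase regulator (0.56 against 0.23), DLEU1 (0.76 against 0.49), and a 5′ untranslated exon of PON2, a paraoxonase (0.40 against 0.03). Lower in LM2 were a 108-nt coding exon of EHBP1, an endocytic adaptor (0.48 against 0.73), a 75-nt coding exon of the splicing factor ZRANB2 (0.39 against 0.62), and a 135-nt coding exon of SERPINB6 (0.12 against 0.33).

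Several genes of antigen presentation had fewer event reads in LM2; they are named as single genes and not as a tested group. CD74 was lower in LM2, as were HLA-B (800 reads against 5777, ratio 0.173), HLA-F (0.299) and the class II transactivator CIITA (0.208). The death ligand TNFSF10 (101 against 1319, 0.0957), the mesenchymal cadherin CDH11 (35 against 352, 0.124), BST2 (0.159) and ALPK2 (3 against 301, 0.0125) were also lower. The phospholipases PLCB4 (1968 against 43, ratio 57.2) and PLCB1 (279 against 16, 21.8) were higher, with MISP (935 against 35, 33.4), which binds actin in mitosis, IGFBP1 (2222 against 373, 7.44), the zinc finger protein ZNF521 (12.2) and EGFR (2.08).

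Calls set by reads inside the exon rather than by exclusion reads could have added to the excess of higher over lower exons, and this was not decided. The 95% interval of the read odds ratio fell wholly short of the odds ratio of the deposited levels in 12.3% of the higher calls (16 of 130, 7.20 to 19.2), PLEC and the 63-nt exon of CD44 among them, and in 0% of the lower calls (0 to 7.71). These intervals overlap, which does not show that the shares are alike. Exclusion reads over both libraries were few, with a median of 9 in higher and 19.5 in lower calls. The read intervals were therefore wide, and the test could miss a shortfall. In a class of 2825 exons, exclusion reads were below 1% of informative reads in each library, so they could hardly set a call. There 56 exons were called higher and 6 lower, which leans towards the explanation. That class needed at least 100 informative and 100 shared reads per library but no exclusion read. Its exons need not be among those tested, so these counts were not part of the test. The sign of the read odds ratio followed the call in 101 of 130 higher and 45 of 46 lower calls. A difference in coverage of GC-rich sequence is argued against as the whole cause, because 82.4% of 34 changed exons with exon minus flank GC content in the middle 20% of tested exons were higher (65.5 to 93.2). Shrinkage of the shallower LM2 library towards 0.5 is argued against too, as 63.1% of the higher exons lay farther from 0.5 in LM2 (54.2 to 71.4). A general rise in inclusion in LM2 was tested among changed exons only, and stays open there. Of the 89 changed exons with a mean read-based level of 0.1 to 0.9, 59.55% were higher, and the interval of 48.6 to 69.8 includes 50. That range is partly set by the change itself, and exons picked as changed cannot speak to a rise over all exons. Over all 14109 tested exons the median difference was 0, with quartiles of -0.02 and 0.03, which shows no shift of the typical exon.

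The PLEC exon was higher in LM2 by its inclusion level, with 0.292 inclusion reads per shared read in LM2 against 0.119 in parental cells. Less skipping in LM2 is argued against, since exclusion reads per shared read were 5.15 times as frequent there (3.10 to 9.04), at 0.168 per 100 shared reads against 0.0326. Coverage of GC-rich sequence is argued against as the whole cause, because 56 other exons of at least 65% GC, with exclusion reads below 1% of informative reads in each library, had a median log2 change of 0.33 in that read ratio, and none reached the 1.29 of PLEC. Coverage of long exons is argued against as the whole cause, with a median of 0.071 over 86 exons of at least 1000 nt under that limit and none at that level, but with no limit on exclusion reads, a check added after the data were seen, 1 of 125 long exons, that of NIN at 1.46, and 4 of 134 GC-rich exons reached it (medians 0.17 and 0.33). A difference in transcript ends or coverage at PLEC and few other exons could remain, and was not tested.

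Lower HLA-B and CD74 reads could reflect a lower interferon response in LM2, and this could not be decided. Over 54 measured interferon-stimulated genes, with BST2, HLA-B, TNFSF10, CD74 and CD40 that prompted the test included, 11 were at least 2-fold lower and 2 were higher, and the median log2 ratio of -0.16 lay at the 28.98 percentile of random lists. Those 5 genes were picked for being low, so they draw this median down by construction, and it cannot count towards the explanation. Without those 5 genes, 6 of 49 were lower and 2 higher, and the median of -0.10 lay at the 58.9 percentile. As a set, these 49 genes were thus not low in LM2, although single members were. DDX60 (0.361), XAF1 (0.387) and MX2 (0.402), which lie outside antigen presentation, were among the lower, and IFI27, with 230 event reads, was listed for parental cells only and so is not among the 54. IFIT3 (ratio 1.74), SP110 (2.43) and TRIM5 (2.41) lay on the high side, while TAPBP (0.785) and PSME2 (1.18), of antigen presentation, were not 2-fold lower, and 1 pooled library stood for each line.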
